A study of Mus musculus with 9 samples.

How the data were processed

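RNA was measured by sequencing in 9 mouse livers. Per the labels' protocols, total RNA was purified with a column kit and libraries were made with a directional kit, which keeps the strand of each transcript. The deposited table holds whole-number counts of reads per gene, made by the authors and not normalised. Per the submitters' processing notes, the tools named are cutadapt 3.0, STAR 2.7.8a, HTSeq 0.11.2 and DESeq2 1.30.0, with the mm10 build. The strand setting of the counting and the annotation release are not given in the sources used here.

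The table has 21703 rows, of which 21702 are Ensembl gene identifiers and 1 is the reporter sequence IRES-mCherry. Symbols were found for 21588 identifiers and not for 114. Where a symbol belonged to several identifiers, it was given to the identifier with the most counts. Gene positions and transcript lengths came from GENCODE M21, which uses GRCm38, the assembly that mm10 names. Of the rows, 21551 are protein coding there. In all libraries, several mitochondrially encoded genes that have nuclear copies had almost no counts, so reads that match several places may not have been counted. Values of genes with near-identical copies are therefore uncertain, among them ribosomal proteins, histones, globins, the Mup, Serpina3, Cyp2c, Cyp4a12, Ugt2b and Saa genes. Reads of the Myc and Mycl transgenes carry the coding sequence of the mouse genes and cannot be separated from those of the resident genes in these counts.

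Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the group as its argument and a minimum count of 10, which left 12651 genes. Library sizes were scaled by TMM. Values in counts per 1e+06 (CPM) use these scaled sizes and are given as mean ± SD over 3 livers. Dispersions were estimated over all 9 libraries, which leaves 6 residual degrees of freedom, and each comparison was a contrast of a quasi-likelihood fit (glmQLFit, glmQLFTest). P-values were adjusted by the Benjamini-Hochberg method over all tested genes, and an adjusted p under 0.05 was counted as changed. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Total counts ran from 11013412 to 20079232 per liver. Library depth sets the precision of low counts, and 3 livers a group set that of the comparisons.

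Before the data were examined, 40 gene lists and a rule for naming genes were fixed. The rule takes, per comparison and direction, the 12 genes with the largest fold change that were changed, had a mean above the median tested gene (17.6 CPM) and whose groups did not overlap, without clone-type names. It adds up to 4 members of each list with the smallest adjusted p, and always Myc, Mycl, Mycn and Max. Lists were tested with limma 3.58.1 camera at a preset correlation of 0.01 between genes, on log2 CPM with a prior count of 2, and adjusted over the 40 lists. No list passed in any of the 3 comparisons with a correlation estimated from the data, and that adjusted p is given with the lists described. The fry test, which asks whether the genes of a list move on balance in a single direction, was the other alternative.

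The procedure was tested on simulated data, with counts drawn from the means, dispersions and depths of these libraries over 10 draws, in which 200 genes were changed. For the simulated Mycl against no dox comparison, run on 12507 to 12565 genes, 47.7% of genes changed by 2-fold and 93.2% of those changed by 4-fold were recovered, and 5.09% of calls were false. The simulated c-Myc against no dox comparison, on 12487 to 12549 genes, gave 46.8%, 93.0% and 4.22%. For the simulated c-Myc against Mycl comparison, on 12514 to 12563 genes, the values were 47.8%, 92.6% and 4.46%. A list raised by 1.5-fold was called in 10 of 10 draws for each comparison. Over the 10 draws, each with 39 unchanged lists, 3, 0 and 1 of those were called falsely in the same order of comparisons. Each gene was drawn independently of the others. In the data the estimated correlation was 0.42 for DNA replication genes and 0.92 for cytosolic ribosomal proteins. The draws therefore cannot show how often camera at the preset correlation calls unchanged lists of correlated genes. Each gene also had the same dispersion in all 3 groups of the draws, whereas replicates in the data were closest in the controls. The shares of recovered genes and of false calls thus hold for groups of equal spread. They do not show the share of false calls in these data, least of all for c-Myc against Mycl.

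The alternatives were other scalings, other filters, a 1.5-fold threshold (glmTreat), DESeq2 1.42.0, limma-voom, fits of the 6 libraries compared, a replicate block and leaving out each library. Removal of a transcript length trend, library weights and list tests under further scalings were added after seeing the data. The alternatives fixed for normalised values did not apply, because the table holds counts. Pairs of replicates differed by far more than sampling noise, with a chi-square per degree of freedom of 10.5 to 207, so no library was counted as a duplicate. The labels name separate livers; they do not state litters or days, so p-values measure the spread between these samples. Figures were drawn with matplotlib 3.10.9.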

Results

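Liver RNA was sequenced from 9 mice aged 4 weeks, in 3 groups of 3. Doxycycline switches on the transgenes of these mice through a tetracycline-responsive promoter. The control livers carried inducible Mycl and received no doxycycline. The Mycl livers had the same genotype and were taken 48 h after an injection of 0.2 ml doxycycline at 2.0 mg/ml. The c-Myc livers came from a line with inducible c-Myc and were treated in the same way. Mycl and c-Myc are transcription factors of the MYC family, and each transgene is followed by an IRES-mCherry reporter. Total counts per library were 14043323 to 20079232 in the control livers, 11013412 to 18887413 in the Mycl livers and 14088780 to 16482480 in the c-Myc livers. No group received doxycycline without a transgene, and no untreated liver of the c-Myc line was analysed here.

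The transgenes were measured first, as a check of the labels. IRES-mCherry stood at 0.576 ± 0.449 CPM in the control livers (SD, n = 3), 156 ± 109 CPM in the Mycl livers and 193 ± 106 CPM in the c-Myc livers. Mycl (ENSMUSG00000028654; chromosome 4, 122995652 to 123002485, GRCm38) stood at 11.3 ± 0.397 CPM in controls and 138 ± 92.5 CPM in Mycl livers, a log2 fold change of 3.61 (SE 0.46, edgeR adjusted p = 0.00756). Myc (ENSMUSG00000022346; chromosome 15, 61985391 to 61990374) stood at 7.91 ± 4.37 CPM in controls and 189 ± 96.5 CPM in c-Myc livers, a log2 fold change of 4.59 (SE 0.61, edgeR adjusted p = 0.00102). Every library matched its label. The reporter did not pass the test between c-Myc and Mycl livers, with a log2 fold change of 0.31 (SE 0.58, edgeR adjusted p = 0.764). Mycn and Max, the shared partner of MYC proteins, passed in none of the 3 comparisons.

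**Figure D1:**
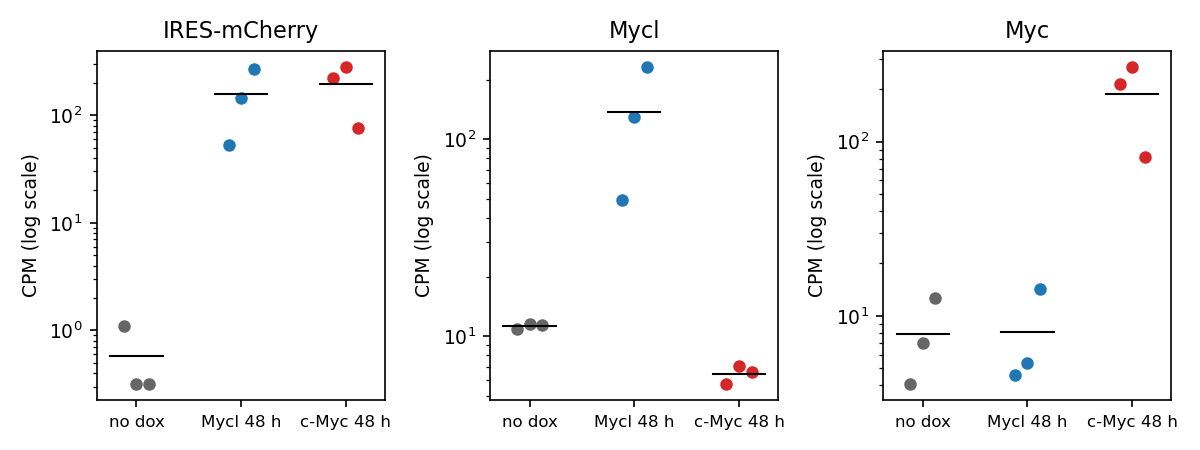
CPM of IRES-mCherry, Mycl and Myc in each liver on log axes, with points for livers and black lines for group means (n = 3 each). The reporter is at or below 1.09 CPM in the control livers and at or above 52.3 CPM in all treated livers.

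The first comparison asked what 48 h of Mycl changed in the liver. Some genes of mitosis and DNA replication rose, in numbers that depended on the tool. Of 30 measured genes of mitosis, 23 rose and 7 did not pass, and 30 rose when adjusted over the list alone; Birc5, a regulator of chromosome segregation, rose by 3.02 on the log2 scale (SE 0.42) and the kinase Cdk1 by 1.94 (SE 0.30). Of 34 DNA replication genes, 11 rose and 23 did not pass, and 28 rose adjusted over the list alone, among them Gins2 at 3.23 (SE 0.47) and the ligase Lig1 at 1.90 (SE 0.27). Both lists passed camera, with an adjusted p = 1.29e-27 and 4.94e-18, and neither did with an estimated correlation (adjusted p = 0.336 for both). Fewer genes passed without control replicates 1, 2 and 3 (0, 9 and 3 of mitosis; 1, 5 and 2 of DNA replication) and without Mycl replicate 3 (6 in each list), and 17 of DNA replication passed without Mycl replicate 1. DESeq2 called 28 mitosis and 24 DNA replication genes higher, and limma-voom 7 and 5. Both lists passed camera whichever single library was left out.

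Genes of the acute phase response, whose proteins the liver secretes in inflammation, changed in part. Of 24 acute phase response genes, 7 rose, 1 fell and 16 did not pass (15 rose and 1 fell adjusted over the list alone). Lcn2, a secreted iron-carrier binding protein, rose from 6.78 ± 2.39 to 159 ± 124 CPM (ENSMUSG00000026822; chromosome 2, 32384633 to 32388252; log2 fold change 4.57, SE 0.73, edgeR adjusted p = 0.0156), and Orm2 rose by 3.31 (SE 0.45). Hamp, which encodes the iron hormone hepcidin, fell by 1.60 (SE 0.28). The list passed camera (adjusted p = 1.15e-07; adjusted p = 0.336 with an estimated correlation). Of 11 genes of the neutrophils and monocytes list, 3 rose and 8 did not pass, with 5 higher and 1 lower adjusted over the list alone. The 3 were Ccl2, a chemokine for monocytes, at 3.10 (SE 0.35), its receptor Ccr2 at 2.39 (SE 0.27) and Itgam at 1.93 (SE 0.28). The list had a camera adjusted p = 0.000378 and an adjusted p = 0.336 with an estimated correlation. Ccl2 stood at 0.192 ± 0.0528 CPM in controls and 1.71 ± 0.104 CPM in Mycl livers, so its fold change rests on few reads. The cell cycle inhibitor Cdkn1a rose from 4.97 ± 0.794 to 40.7 ± 13.0 CPM (log2 fold change 3.04, SE 0.38), within a list of 19 p53 targets and apoptosis genes of which 3 rose and 16 did not pass (6 rose adjusted over the list alone; camera adjusted p = 0.00199; adjusted p = 0.488 with an estimated correlation). Without control replicates 1, 2 and 3, 1, 2 and 2 acute phase response genes rose, without Mycl replicate 3 it was 4, and 12 without Mycl replicate 1 or 2; 1 gene of p53 targets and apoptosis rose without any single control or without Mycl replicate 3, and 5 of neutrophils and monocytes without Mycl replicate 2. DESeq2 called 13 acute phase response and 6 p53 targets and apoptosis genes higher, and limma-voom 4 and 1.

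Of 15 Kupffer cells and macrophages genes, 1 rose and 14 did not pass (6 rose adjusted over the list alone; camera adjusted p = 0.0091; adjusted p = 0.505 with an estimated correlation): Marco, a scavenger receptor gene, at 1.38 (SE 0.31). DESeq2 called 3 higher and limma-voom 0; 0 rose without any single control or Mycl replicate 3 and 3 without Mycl replicate 1 or 2, and the list did not pass camera without control replicate 1 (adjusted p = 0.0546), without Mycl replicate 3 (adjusted p = 0.0716) or with the length trend removed (adjusted p = 0.251). Of 16 genes of liver sinusoidal and vascular endothelium, 0 passed by edgeR, also adjusted over the list alone, and 0 by DESeq2 or limma-voom; 3 were lower at an unadjusted p under 0.05. That list passed camera towards lower values (adjusted p = 0.00455; adjusted p = 0.529 with an estimated correlation), and not without Mycl replicate 1 (adjusted p = 0.14).

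Of 79 cytosolic ribosomal proteins, 24 rose and 55 did not pass, and 79 rose adjusted over the list alone, with a median log2 fold change of 1.27 and Rps28 at 1.05 (SE 0.18) and Rpl30 at 0.90 (SE 0.17) (camera adjusted p = 2.89e-34; adjusted p = 0.429 with an estimated correlation). Their median against the controls was 2.02 in Mycl replicate 1, 0.44 in replicate 2 and 0.90 in replicate 3. Replicate 1 also had high values for short transcripts in general: genes with a longest transcript under 800 nt had a median of 1.46 there, and at most 0.26 in the other 8 libraries. Ribosomal protein genes were not left out of these 242 genes, so that median is not separate from theirs. The larger class of 1118 genes of 800 to 1500 nt had at most 0.09 in the other 8 libraries and 0.70 in Mycl replicate 1. Without that library the cytosolic ribosomal proteins had a median of 0.74 and 56 rose; 77 rose without Mycl replicate 2, 1 without Mycl replicate 3 and 0 without any single control, and the list passed camera each time. DESeq2 called 76 higher and limma-voom 17. Of 40 genes of oxidative phosphorylation, 0 passed by edgeR, adjusted over all genes or adjusted over the list alone, and 0 by DESeq2 or limma-voom; 1 was lower at an unadjusted p under 0.05. Their list passed camera (adjusted p = 0.0172; adjusted p = 0.723 with an estimated correlation); without replicate 1 it did not pass (adjusted p = 0.631), nor without control replicate 3 (adjusted p = 0.0761).

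**Figure D2:**
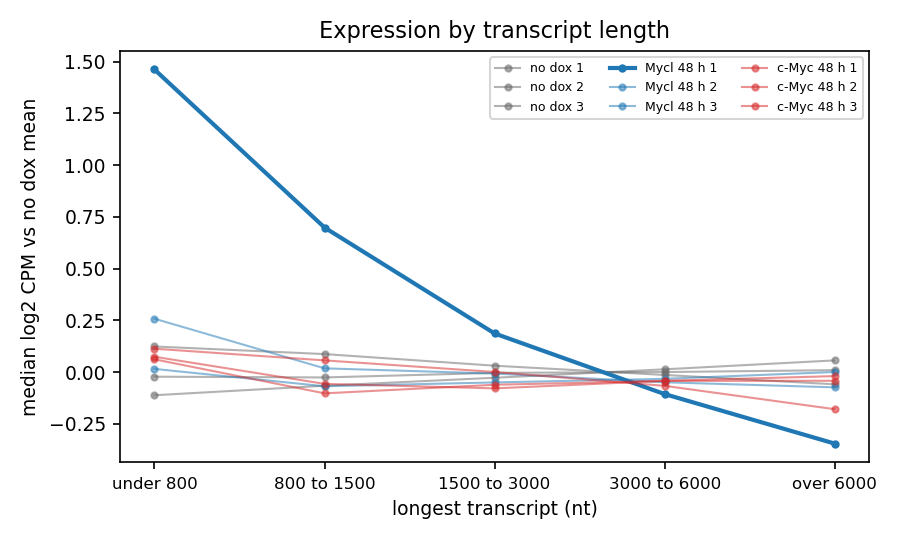
Median log2 CPM relative to the mean of the control livers (y axis) for genes in 5 classes of longest transcript length in nt (x axis), with a line per library. The bold line is Mycl replicate 1, which runs from 1.46 for genes under 800 nt to -0.35 for genes over 6000 nt. Ribosomal protein genes were not left out of the classes.

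Some genes of fatty acid oxidation, of pericentral hepatocytes and with male-biased expression fell, and most did not pass. Of 25 fatty acid oxidation genes, 4 fell and 21 did not pass (11 fell adjusted over the list alone), with Ehhadh, a peroxisomal enzyme, at -1.04 (SE 0.20) and Cpt2, a mitochondrial enzyme, at -0.72 (SE 0.15). Of 14 pericentral hepatocytes genes, 3 fell and 11 did not pass (8 fell adjusted over the list alone): Tbx3 at -1.58 (SE 0.23), Axin2 at -1.32 (SE 0.23) and Rnf43 at -0.94 (SE 0.20), which are known as targets of Wnt signalling. These lists passed camera, with an adjusted p = 6.04e-08 and 1.52e-07, and had an adjusted p = 0.336 with an estimated correlation. Of 16 male-biased liver genes, 4 fell and 12 did not pass (6 fell adjusted over the list alone; camera adjusted p = 1.99e-06; adjusted p = 0.482 with an estimated correlation). Cyp4a12a, a fatty acid hydroxylase, fell from 270 ± 44.3 to 44.0 ± 14.3 CPM (ENSMUSG00000066071; chromosome 4, 115299046 to 115332815; log2 fold change -2.61, SE 0.30, edgeR adjusted p = 0.00464). The male-biased median was -3.63 in Mycl replicate 3 against -0.44 and -0.47 in replicates 1 and 2, and the fold change had a median of -0.37 without replicate 3. With control replicates 1, 2 and 3 left out in turn, fatty acid oxidation had 0, 0 and 0 genes that fell, pericentral hepatocytes 0, 2 and 1, and male-biased liver genes 1, 1 and 1; without Mycl replicate 3 it was 1, 1 and 2. Without Mycl replicate 2, 5 pericentral hepatocytes genes fell. DESeq2 called 10 fatty acid oxidation and 8 pericentral hepatocytes genes lower, and limma-voom 2 and 3. The lists passed camera each time.

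Camera passed 21 of the 40 lists, not all of them described here. In all, 283 genes were higher and 122 lower in Mycl than in control livers by edgeR, of 12651 tested. Groups did not overlap for 29.4% of genes, where chance gives 10%. The counts depended on single libraries: 17 higher and 9 lower passed without control replicate 1, 63 and 18 without control replicate 3, 82 and 20 without control replicate 2, and 110 and 27 without Mycl replicate 3, against 471 and 127 without Mycl replicate 1 and 539 and 178 without Mycl replicate 2. Library totals gave a share of higher calls of 83.2% and upper-quartile factors 82.7%, in place of 69.9%; the median of all genes moved from 0.01 to 0.14 with library totals.

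The second comparison asked the same of c-Myc. Genes of ribosome biogenesis, DNA replication, mitosis and nucleotide synthesis rose. Of 45 ribosome biogenesis genes, 40 rose and 5 did not pass (42 rose adjusted over the list alone), with the nucleolar proteins Npm1 at 2.24 (SE 0.24) and Ncl at 2.05 (SE 0.28). Of 34 DNA replication genes, 32 rose and 2 did not pass (32 adjusted over the list alone), with the helicase subunit Mcm5 from 5.68 ± 1.99 to 72.9 ± 23.1 CPM (ENSMUSG00000005410; chromosome 8, 75109569 to 75128439; log2 fold change 3.68, SE 0.33, edgeR adjusted p = 0.000335) and Uhrf1, a factor of DNA methylation maintenance, at 5.06 (SE 0.50). Of 30 mitosis genes, 29 rose and 1 did not pass (29 adjusted over the list alone), with Cdk1 at 2.92 (SE 0.30). Of 31 genes of nucleotide and polyamine synthesis, 23 rose and 8 did not pass (24 adjusted over the list alone), with the ribonucleotide reductase subunit Rrm2 at 3.40 (SE 0.31). The camera adjusted p was 2.71e-19, 4.2e-26, 6.46e-25 and 6.53e-14 in that order, and each had an adjusted p = 0.297 with an estimated correlation.

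Of 79 cytosolic ribosomal proteins, 34 rose and 45 did not pass (47 rose adjusted over the list alone; camera adjusted p = 1.92e-17; adjusted p = 0.415 with an estimated correlation). Of 31 translation factors, 12 rose and 19 did not pass (16 rose adjusted over the list alone; camera adjusted p = 2.91e-06; adjusted p = 0.297 with an estimated correlation). Of 19 p53 targets and apoptosis genes, 8 rose and 11 did not pass (8 adjusted over the list alone; camera adjusted p = 9.58e-05; adjusted p = 0.297 with an estimated correlation), with Eda2r, a receptor of the TNF receptor family, at 4.12 (SE 0.51), Cdkn1a at 3.07 (SE 0.38) and the death receptor gene Tnfrsf10b at 2.94 (SE 0.43). Leaving out any single control or c-Myc replicate 1 or 2 gave 11 to 20 cytosolic ribosomal proteins and 3 to 6 translation factors that rose. DESeq2 called 54 cytosolic ribosomal proteins higher and limma-voom 39. Serpina3c, a serine protease inhibitor gene with near-identical neighbours, rose from 0.488 ± 0.336 to 151 ± 157 CPM (log2 fold change 8.35, SE 1.15, edgeR adjusted p = 0.00124).

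Some genes of several metabolic lists and of both liver zones fell. Of 31 genes of urea cycle and amino acid catabolism, 14 fell and 17 did not pass (19 fell adjusted over the list alone), with Hpd, an enzyme of tyrosine breakdown, at -1.22 (SE 0.27). Of 25 fatty acid oxidation genes, 14 fell and 11 did not pass (1 rose and 16 fell adjusted over the list alone), with Ehhadh at -1.50 (SE 0.21). Both had a camera adjusted p = 3.71e-07, and with an estimated correlation an adjusted p = 0.35 and 0.297. Of 18 genes of bile acid synthesis and transport, 7 fell and 11 did not pass (13 fell adjusted over the list alone; camera adjusted p = 3.06e-05; adjusted p = 0.297 with an estimated correlation), with the bile salt export pump Abcb11 at -1.39 (SE 0.30). Of 14 pericentral hepatocytes genes, 7 fell and 7 did not pass (12 fell adjusted over the list alone; camera adjusted p = 4.45e-06; adjusted p = 0.297 with an estimated correlation). Of 14 periportal hepatocytes genes, 4 fell, 1 rose and 9 did not pass (7 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.0082; adjusted p = 0.423 with an estimated correlation), with the growth factor gene Igf1 at -1.01 (SE 0.21) and Hsd17b13, a lipid droplet protein gene, at 0.83 (SE 0.21). Of 33 cytochrome P450 and conjugation enzymes, 10 fell, 1 rose and 22 did not pass (13 fell and 1 rose adjusted over the list alone; camera adjusted p = 4.93e-05; adjusted p = 0.309 with an estimated correlation); Aox3, an aldehyde oxidase, fell from 2376 ± 175 to 472 ± 175 CPM (ENSMUSG00000064294; chromosome 1, 58113130 to 58200698; log2 fold change -2.33, SE 0.32, edgeR adjusted p = 0.0012). Without any single control or c-Myc replicate 1 or 2, 2 to 4 genes of urea cycle and amino acid catabolism fell, 3 to 6 of fatty acid oxidation, 1 to 3 of bile acid synthesis and transport and 2 to 4 of cytochrome P450 and conjugation enzymes. Of pericentral hepatocytes 4 fell without control replicate 3 or c-Myc replicate 2. Of periportal hepatocytes 0 fell without control replicate 2, 1 without control replicate 1 or 3 or c-Myc replicate 1 or 2, and 7 without c-Myc replicate 3; only without the last did 1 rise. These lists passed camera each time.

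Some markers of other cells and some genes of the interferon response passed as well. Of 8 erythroid cells genes, 6 fell and 2 did not pass (8 fell adjusted over the list alone), with a median of -2.03 and Slc4a1, the anion exchanger of red cells, at -3.79 (SE 0.58). Of 19 interferon response genes, 10 fell, 1 rose and 8 did not pass (12 fell and 1 rose adjusted over the list alone), with Ifih1, an RNA sensor, at -1.02 (SE 0.15) and the chemokine Cxcl10 at 1.48 (SE 0.27). Both lists had an adjusted p = 0.297 with an estimated correlation, and camera gave an adjusted p = 6.19e-05 and 2.27e-05. Of 11 neutrophils and monocytes genes, 3 rose, 1 fell and 7 did not pass (4 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.00691; adjusted p = 0.297 with an estimated correlation), with Ccl2 at 3.88 (SE 0.33) and Il1b, a cytokine gene, at -1.08 (SE 0.32). With library totals the list did not pass camera (adjusted p = 0.0831). Ccl2 rests on few reads, at 0.192 ± 0.0528 CPM in controls and 2.94 ± 0.612 CPM in c-Myc livers. Without any single control or c-Myc replicate 1 or 2, 2 to 3 erythroid cells genes and 0 neutrophils and monocytes genes fell, and 4 interferon response genes fell without control replicate 2 or c-Myc replicate 2. Of 15 Kupffer cells and macrophages genes, 2 fell and 13 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.028; adjusted p = 0.432 with an estimated correlation), with Clec4f, a lectin gene, at -0.81 (SE 0.20). Of 16 genes of liver sinusoidal and vascular endothelium, 1 fell and 15 did not pass (1 fell adjusted over the list alone; camera adjusted p = 0.00691; adjusted p = 0.423 with an estimated correlation): Dnase1l3, a nuclease gene, at -0.84 (SE 0.22). In both lists 0 fell without any single control or c-Myc replicate 1 or 2 and 0 with library totals, and 3 of the endothelium fell without c-Myc replicate 3. The Kupffer cells and macrophages did not pass camera without control replicate 2 (adjusted p = 0.0537) or c-Myc replicate 2 (adjusted p = 0.0529).

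**Figure D3:**
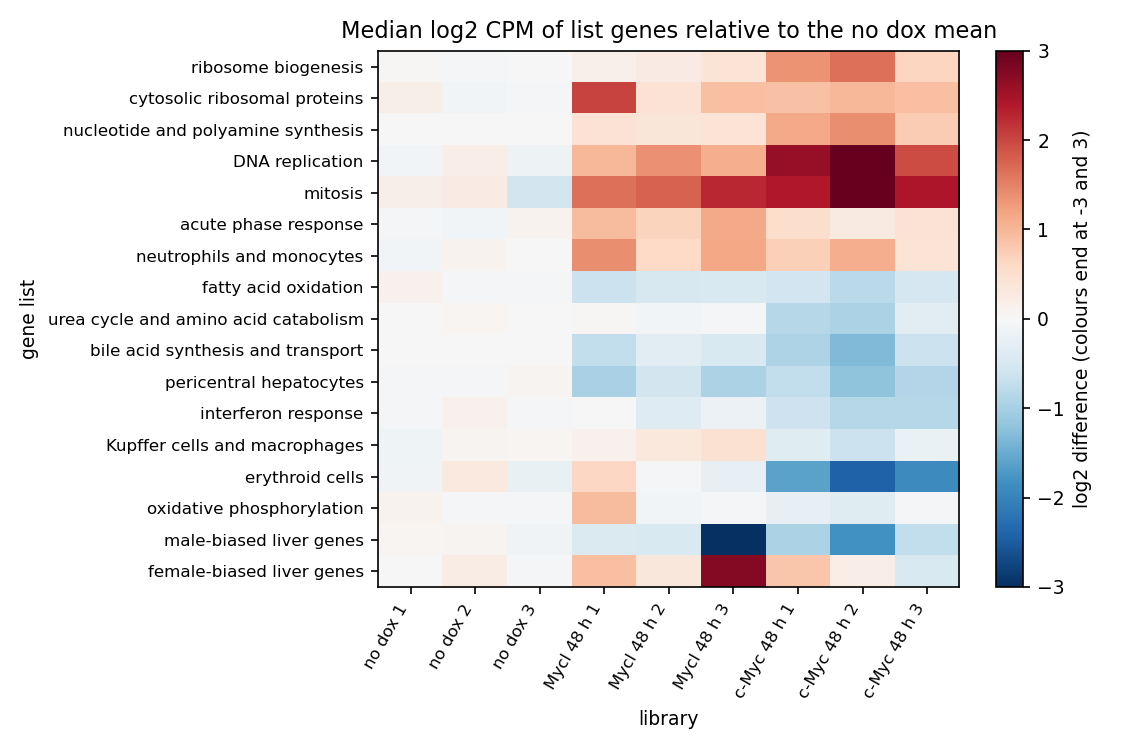
Median log2 CPM of 17 gene lists (rows) in each of the 9 livers (columns), relative to the mean of the control livers; red is higher and blue lower, and colours end at -3 and 3. DNA replication reaches 1.95 to 3.02 in the c-Myc livers and at most 1.36 in the Mycl livers.

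Camera passed 28 of the 40 lists, not all of them described here. In c-Myc livers 1490 genes were higher and 1124 lower than in controls by edgeR, and groups did not overlap for 50.7% of genes (chance gives 10%). Leaving out single libraries gave 897 to 1704 higher and 300 to 1296 lower genes: 975 and 383 without control replicate 1, 910 and 310 without control replicate 2, 941 and 334 without control replicate 3, 897 and 300 without c-Myc replicate 2, and 451 lower without c-Myc replicate 1. With library totals the median of all genes moved from -0.05 to 0.31 and 90.4% of calls were higher, in place of 57%.

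The third comparison set c-Myc directly against Mycl livers. Some ribosome biogenesis genes were higher with c-Myc: 25 of 45 were higher and 20 did not pass (40 higher adjusted over the list alone), with a median log2 difference of 0.92; Rrp12, a ribosome export factor, was at 43.4 ± 21.7 CPM against 11.6 ± 4.50 CPM (ENSMUSG00000035049; chromosome 19, 41862851 to 41896173; log2 fold change 1.89, SE 0.40, edgeR adjusted p = 0.0296). Of 34 DNA replication genes, 22 were higher and 12 did not pass (30 adjusted over the list alone), and of 31 genes of nucleotide and polyamine synthesis, 14 were higher and 17 did not pass (18 adjusted over the list alone), with the polyamine enzyme Srm at 1.83 (SE 0.30) and, for DNA replication, the licensing factor Cdt1 at 2.17 (SE 0.33). The camera adjusted p was 3.04e-18 for the ribosome biogenesis and DNA replication lists and 7.74e-10 for the nucleotide list, and with an estimated correlation the adjusted p was 0.53, 0.523 and 0.523. Without c-Myc replicate 1 or 2, 0 ribosome biogenesis, 1 DNA replication and 2 nucleotide and polyamine synthesis genes were higher by edgeR; without Mycl replicate 3 it was 9, 9 and 6, and 5 of ribosome biogenesis without Mycl replicate 2. DESeq2 called 35 ribosome biogenesis genes higher and limma-voom 15. The lists passed camera each time.

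Of 15 Kupffer cells and macrophages genes, 5 were lower and 10 did not pass (10 lower adjusted over the list alone), with the complement gene C1qb at -0.85 (SE 0.13), and the list median was below that of every control in all 3 c-Myc livers and above it in all 3 Mycl livers. Of 8 erythroid cells genes, 4 were lower and 4 did not pass (6 lower adjusted over the list alone), the globin gene Hba-a1 at -2.45 (SE 0.39) among them, and of 31 genes of urea cycle and amino acid catabolism, 5 were lower and 26 did not pass (23 lower adjusted over the list alone), with Got1, an aminotransferase gene, at -1.15 (SE 0.24). The camera adjusted p was 1.42e-06, 2.79e-06 and 1.17e-10, and with an estimated correlation the adjusted p was 0.523, 0.523 and 0.532. Without c-Myc replicate 1 and 2 in turn, 0 and 0 Kupffer cells and macrophages, 1 and 0 erythroid cells and 0 and 0 urea cycle and amino acid catabolism genes were lower. Without Mycl replicate 3 it was 1 for the Kupffer cells and macrophages and 0 for the urea list, without Mycl replicate 1 it was 9 for the former, and the latter had 1 without Mycl replicate 2 and 23 without c-Myc replicate 3; camera calls held each time. DESeq2 called 16 genes of the urea list and 9 of the Kupffer cells and macrophages lower, and limma-voom 6 and 5. Lpin1, a phosphatidate phosphatase, was at 60.9 ± 6.95 CPM with c-Myc and 275 ± 28.3 CPM with Mycl (ENSMUSG00000020593; chromosome 12, 16535669 to 16610966; log2 fold change -2.17, SE 0.18, edgeR adjusted p = 0.000759). Tff3, a secreted trefoil peptide, was at 6.34 ± 0.753 CPM against 64.3 ± 31.9 CPM.

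Camera passed 22 of the 40 lists, not all of them described here. By edgeR, 524 genes were higher and 333 lower in c-Myc than in Mycl livers, with groups that did not overlap for 25.7% of genes (chance gives 10%). The counts depended on the libraries used: a fit of the 6 libraries alone gave 35 and 39, leaving out c-Myc replicate 1 gave 40 and 27, c-Myc replicate 2 gave 47 and 32, Mycl replicate 3 gave 183 and 190, Mycl replicate 2 gave 262 higher, and c-Myc replicate 3 gave 979 and 572. With library totals 86.7% of calls were higher, in place of 61.1%, and the median of all genes moved from -0.03 to 0.20.

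The effects of Mycl and c-Myc were then compared gene by gene. Of the genes higher with Mycl, 253 were also higher with c-Myc, and 89 were lower with both; 2 went in opposite directions. Independent lists of these sizes would share 33.3 and 10.8 genes. The log2 fold changes correlated across genes, which are not independent replicates, with Pearson's r = 0.667 and a covariance of 0.342. Both comparisons use the same 3 controls, and 50 simulations of unchanged groups gave a mean r of 0.504, a covariance of 0.0463 and 0 shared calls. These simulations called at most 2 genes higher and 1 lower per comparison, so their 0 shared calls give no baseline for the overlap. The covariance lay 0.296 above the simulated one. The simulations gave each gene the same dispersion in all groups, whereas the real control livers were closer to each other than the treated livers. The simulated r and covariance are therefore no exact baseline for what the shared controls give in these data. The 3 controls cannot be split into parts of at least 2, so part of the excess of shared calls may come from the shared controls. Both treated groups also received doxycycline and the controls did not. Shared changes therefore cannot be told apart from effects of doxycycline or its injection.

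**Figure D4:**
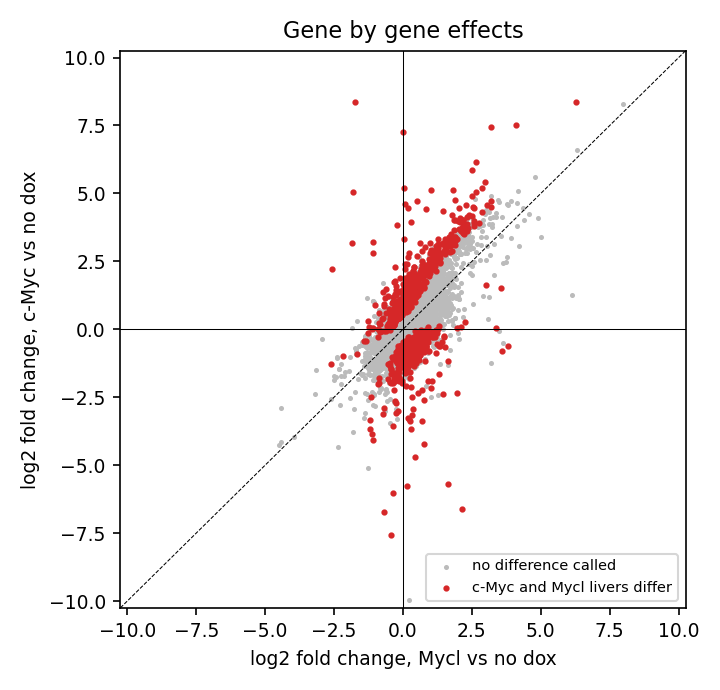
Log2 fold change against control livers for each of 12651 genes, Mycl on the x axis and c-Myc on the y axis; red points are genes that differ between c-Myc and Mycl livers, and the dashed line marks equal effects. Across genes Pearson's r is 0.667.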

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

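The tests of explanations and the counts of other splits in this part were chosen after the results were seen, while the tests of the difference between c-Myc and Mycl livers were not. The genes and lists below were picked because the direct test between c-Myc and Mycl livers, by edgeR for genes and by both camera and fry for lists, found that their effects differ. Values are log2 differences, c-Myc minus Mycl. Higher with c-Myc were Serpina3c at 10.1, Myc at 4.53, Uhrf1 at 2.43, Rrp12 at 1.89, Hells at 1.86, Cad at 1.84, Srm at 1.83, Pole at 1.80, Rrm2 at 1.72, and Mcm4, Vars and Mcm3 at 1.68 each. Lower with c-Myc were Mycl at -4.42, Cyp7a1 at -4.30, Tff3 at -3.34, Hbb-bs at -2.97, Cyp2c69 at -2.72, Bhmt and Cyp2c40 at -2.48 each, Hba-a1 at -2.45, Slc22a7 at -2.20, Lpin1 at -2.17, Upp2 at -2.04 and Tcim at -1.98. Serpina3c rests on under 1 CPM in each of the 6 other livers and ranged from 14.0 to 323 CPM with c-Myc. Cyp7a1 stood at 666 CPM in Mycl replicate 3 and at 62.3 and 65.5 CPM in the other Mycl livers. The list medians were 0.92 for ribosome biogenesis, 0.73 for nucleotide and polyamine synthesis, 1.43 for DNA replication, -0.86 for mitochondrially encoded genes, -0.65 for urea cycle and amino acid catabolism, -0.70 for interferon response, -0.72 for Kupffer cells and macrophages, -2.22 for erythroid cells and -0.32 for sex-linked genes. With an estimated correlation none of them passed camera: the adjusted p was 0.532 for mitochondrially encoded genes and sex-linked genes, 0.53 for interferon response, and 0.523 to 0.532 for the others. Without Mycl replicate 2 or c-Myc replicate 2, and with library totals, the sex-linked genes did not pass camera (adjusted p = 0.0698, 0.0813 and 0.0787). Of 4 sex-linked genes, 0 passed by edgeR, DESeq2 or limma-voom (2 lower adjusted over the list alone). Of 19 interferon response genes, 5 were lower, 1 higher and 13 did not pass by edgeR. DESeq2 called 9 of them lower and 1 higher, and limma-voom 5 and 1. Of 8 mitochondrially encoded genes, 3 were lower and 5 did not pass by edgeR, with 7 lower by DESeq2 and 4 by limma-voom.

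Of 45 ribosome biogenesis genes, 25 were higher in c-Myc than in Mycl livers and 20 did not pass; 0 were higher without c-Myc replicate 1 or 2, and the list did not pass camera with an estimated correlation (adjusted p = 0.53). With the log2 reporter CPM as a covariate over the 6 treated livers, the difference of the list's score was 0.834 (SE 0.216), against 0.945 (SE 0.309) without it. That fit assumes the same slope in both lines, which 6 livers cannot check. By liver, the score was 0.14 to 0.42 with Mycl and 0.64 to 1.65 with c-Myc. The c-Myc liver with the least reporter (76.4 CPM) had 0.64, and the Mycl liver with the most (270 CPM) had 0.42. Within that limit, the values argue against more transgene expression in the c-Myc livers as the whole cause. The lowest median under 4 other scalings was 0.90, which argues against the scaling. The genes that differ lie on 13 chromosomes, so they do not all lie in a few linked segments of the c-Myc line. A linked difference that acts on genes elsewhere would give the same spread, so this does not count against a line effect. A difference between the proteins remains a hypothesis, since line and transgene go together in this design and no untreated c-Myc liver was analysed here.

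Mycl replicate 1 had high ribosomal protein and oxidative phosphorylation genes, and with them short transcripts in general. Its reporter level, 52.3 CPM, was the lowest of the Mycl livers, which argues against more transgene expression there. Removing a length trend, fitted outside the ribosomal protein list, took the median excess over the other Mycl livers from 1.27 to 0.590 for ribosomal proteins and from 0.967 to 0.245 for oxidative phosphorylation, with highest values of 0.203 and 0.132 in other libraries. The medians of replicate 1 stayed above those highest values, so the fitted trend did not take away all of the excess. The lower quartiles of its genes, 0.037 and -0.178, lay below them, which the spread between genes alone can give. Whether transcript length accounts for the rest cannot be told from a single such library. A difference in RNA quality may give such a trend and was not measured here.

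Mycl replicate 3 had low male-biased and high female-biased liver genes, with medians of -3.63 and 2.76 against controls; without it the female-biased liver genes did not pass camera for Mycl against no dox (adjusted p = 0.29, against 0.0091 with it, and 0.505 with an estimated correlation). Its summed Y-linked CPM was 0.958 of the mean of the other libraries, which argues against a female sample or one mixed in large part. At 169 CPM it lay below the control and other Mycl livers (179 to 211 CPM) and above the c-Myc livers (125 to 153 CPM). A small admixture is therefore not excluded. After removal of the length trend the male-biased median was -3.61, which argues against that trend. Its reporter level, 269.8 CPM, was the highest of the Mycl livers, but c-Myc replicate 2 had 282 CPM and a male-biased median of -1.81; with a single such liver, transgene level cannot be told apart from a state of this animal.

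The other splits of the 6 libraries of each comparison were also counted. There are 10 splits, too few for a share under 0.05. In each, 1 split, the real one, gave as many genes: 405 genes for Mycl against no dox with 0 in the highest other split, 2614 for c-Myc against no dox with 0, and 857 for c-Myc against Mycl with 3. Every other split mixes the real groups, so their difference enters the spread within groups and lowers the calls. Such counts do not show how many genes a split of like livers would give.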

How the results depend on the processing

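Removal of the transcript length trend, library weights and list tests with upper-quartile factors or without the 50 most abundant genes were chosen after the data were seen. Camera passed 21, 28 and 22 lists for Mycl against no dox, c-Myc against no dox and c-Myc against Mycl; with an estimated correlation it passed 0, 0 and 0, and fry passed 5, 23 and 9. Under the other scalings, the replicate block, the length trend and each library left out, 16 to 30 lists passed. Counts of genes also depended on the setting, and the cause was not tested. Fits without a library have fewer samples, which alone lowers power, but some smaller fits gave more genes. Replicates were closest in the controls, with a chi-square per degree of freedom of 10.5 to 17.2 between pairs. It was 194 and 207 for the pairs with Mycl replicate 1, 57.0 between Mycl replicates 2 and 3, and 39.6 to 66.0 in c-Myc livers. The main fit shares the dispersion of a gene over all groups. Its counts for c-Myc against Mycl thus rest in part on the closer control livers. For Mycl against no dox (283 higher, 122 lower), the 1.5-fold threshold gave 70 and 13, DESeq2 744 and 342, limma-voom 132 and 68, and library weights 810 and 622; 69 were lower with library totals, 78 with upper-quartile factors, 69 with the replicate block and 64 with only the 6 libraries compared. Leaving out single libraries gave 17 to 539 higher and 9 to 178 lower. For c-Myc against no dox (1490 and 1124), library totals gave 3181 and 337, the 1.5-fold threshold 596 and 142, library weights 2804 and 3224, and only the 6 libraries 2325 and 1784; leaving out single libraries gave 897 to 1704 higher and 300 to 1296 lower. For c-Myc against Mycl (524 and 333), the 1.5-fold threshold gave 22 and 22, DESeq2 998 and 745, library weights 1261 and 1004, and only the 6 libraries 35 and 39; 1456 were higher with library totals. There, leaving out single libraries gave 40 to 979 higher and 27 to 572 lower. The direction of effects of cMyc and Mycl across genes gave r = 0.667, or 0.552 by Spearman's rho, and r was 0.61 to 0.70 when single libraries were left out. Over all settings, passing or not passing was unchanged 1457 times for lists and 4687 times for named genes; calls were lost 165 and 1080 times and gained 55 and 8 times. Nearly all named genes were chosen because they passed in the main fit, so few of them could gain a call. Their losses against gains are therefore no measure of the processing. The direction of a list test that passed in either setting turned 3 times; the cause was not tested. The medians were these: oxidative phosphorylation, Mycl against no dox, had a median of 0 without Mycl replicate 1 and up to 0.57 without others; cytosolic ribosomal proteins, c-Myc against Mycl, ranged from -0.63 without Mycl replicate 2 to 0.22 without Mycl replicate 1; and cholesterol synthesis, c-Myc against Mycl, ranged from -0.26 without c-Myc replicate 1 to 0.29 without c-Myc replicate 3. Without the filter on low counts 16408 genes were tested, and 359 and 136 passed for Mycl against no dox. For c-Myc against no dox 1510 were higher and 979 lower, and for c-Myc against Mycl 583 and 357. Whether depth limits the calls of low genes was not tested.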

Other observations

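Some gene groups have not been described so far. In c-Myc livers members of the list of integrated stress and unfolded protein response rose: Phgdh and Psat1, enzymes of serine synthesis, by 5.87 (SE 0.75) and 4.21 (SE 0.48) on the log2 scale by edgeR, with Asns, the asparagine synthetase, at 3.02 (SE 0.48). Phgdh stood at 0.280 ± 0.252 CPM in controls and 15.6 ± 11.6 CPM in c-Myc livers, so the size of its fold change rests on few control reads. In all, 5 of the 20 list genes rose, 2 fell and 13 did not pass (6 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.0526, 0.297 with an estimated correlation, and 0.0321 and 0.0176 without control replicate 3 and c-Myc replicate 2). The collagen gene Col1a1 and the actin gene Acta2 of the stellate cells and fibroblasts list rose by 2.84 (SE 0.52) and 2.82 (SE 0.47), with 4 of 16 genes higher, 1 lower and 11 not passing (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.266; adjusted p = 0.665 with an estimated correlation; 2 higher without control replicate 1 or 2 or c-Myc replicate 2). Of 18 circadian clock genes, 7 fell, 1 rose and 10 did not pass (8 fell and 2 rose adjusted over the list alone; 4 fell and 4 rose with library totals, and 4 fell without control replicate 2 or c-Myc replicate 2), with Dbp at -2.54 (SE 0.44) and Nr1d1 at -1.67 (SE 0.29); the list passed camera (adjusted p = 0.0184; adjusted p = 0.297 with an estimated correlation). In Mycl livers 3 of these 18 genes fell, 1 rose and 14 did not pass, so such changes were not particular to c-Myc. Dbp was at -1.91 (SE 0.43) and Nr1d1 at -1.50 (SE 0.29) there. For Mycl against no dox the list did not pass camera (adjusted p = 0.0754, and 0.429 with an estimated correlation). The time of day of tissue collection is not given in the sources used here.

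This test was chosen after the results had been seen. A hypothesis was that segments of the genome that differ between the lines account for part of the genes that differ between c-Myc and Mycl livers; such genes would then lie near each other more often than random genes. Among 857 such genes there were 423 neighbouring pairs within 1 Mb, 1.105 times the mean of 10000 random draws (permutation p = 5e-04, one-sided). Genes that differ between Mycl and control livers, which are of 1 line, also lay near each other, at 1.177 times (permutation p = 0.011, one-sided), so the excess may come from neighbours that are expressed together. Genes that differ between c-Myc and control livers, which are of different lines, had 1942 pairs, 1.004 times the random mean (permutation p = 0.285, one-sided), which goes against the hypothesis. It does not exclude it, since the 2613 genes of that comparison would dilute a small set of linked genes, so the hypothesis cannot be told apart from shared expression of neighbours.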
